A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

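Genomic DNA of 12 diploid prototrophic populations of the yeast Saccharomyces cerevisiae, sampled on day 33 of an evolution experiment, was compared with genomic DNA of the prototrophic strain FY4 on 12 Agilent arrays with 2 colours each. Per the labels, Cy5 carried the population and Cy3 carried FY4 on every array, so more copies in the population raise the log ratio above 0. No dye swap was made, so a dye effect of a probe is not separated from a difference to FY4. The populations fall into 3 genotypes with 4 populations each: wild type (populations 1 to 4), heterozygous for a deletion of the replication origin ARS228 (populations 5 to 8), and homozygous for it (populations 9 to 12). The growth medium is not given in the sources used here. Each population gave 1 array, and the populations are the replicates.

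Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1, which corrected the background, removed a spatial trend and scaled the dyes, and deposited a processed intensity per spot and channel. The deposited log10 ratio of each spot equals the log10 of processed Cy5 over processed Cy3 intensity. The values table that the authors deposited holds the same ratio as log2, to within 0.0005, with no further centring, and its scale, centring and direction are therefore known. The medians of its log2 columns as deposited were -0.023, -0.029, 0.014 and 0.002 for populations 1 to 4, -0.007, -0.008, -0.002 and -0.01 for populations 5 to 8, and -0.029, -0.01, -0.011 and -0.026 for populations 9 to 12. On populations 2 and 3 the scanner's dye scaling varied between probes with an SD of 0.17 and 0.171 on the log2 scale, against 0.03 to 0.077 on the others.

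From these, log2 of processed Cy5 over Cy3 was taken for each of 41775 probes, control spots and spots marked uneven by the scanner (27 to 2970 per array) were left out, and each array was centred on its median. Saturated spots were kept. Of the probes, 41247 were well above background in both channels on all arrays. Probes carry coordinates but no gene names, and the genome build is not given in the sources used here. Gene models of the R64 assembly were laid on these coordinates, and probe length was correlated with coding sequence at shifted positions. On 14 nuclear chromosomes the strongest negative correlation lay within 80 bp of no shift, with r between -0.066 (XII) and -0.199 (III). Genes were named on these and on the mitochondrial genome only. On chromosomes X and XI the strongest correlation lay 280 and 290 bp away, and no gene was named there. These correlations are weak, so the placement of genes is approximate. All printed coordinates are those of the array.

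A gene's value was the mean over its probes, for the 3893 genes with at least 3 probes that could be named. Group means against FY4 and the 3 differences between genotypes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 12 arrays in 1 fit), with Benjamini-Hochberg adjustment over genes. A gene was called at an adjusted p under 0.05 and an absolute log2 of at least 0.2. Apparent copies per diploid cell are 2 times the ratio to FY4, which takes the FY4 copy number as complete and the ratio as linear. Values per population were compared by exact permutation tests, all 2-sided, over the 70 regroupings of 4 against 4, adjusted over the 3 pairs. The smallest p such a test can give is 0.029. After adjustment over the 3 pairs, 1 fully separated pair alone cannot pass 0.05. A second pair would have to be fully separated too.

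Copy-number segments were found on each array with a least-squares partition (penalty of 30 noise variances per breakpoint, at least 5 probes per segment) in Python 3.11.15 and numpy 2.4.6. Segments of at least 10 probes with an absolute mean log2 of at least 0.2 were called, and the SUL1 amplicon is the unbroken run of such gained segments that holds SUL1. Sums of gained and lost kb count nuclear segments only. A whole chromosome was called at an absolute median of 0.15. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation.

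On simulated data for the heterozygous against wild-type comparison with 3893 genes, the limma step recovered 84 of 100 genes planted at an absolute log2 of 0.3 and 96 of 100 planted at 0.6, with 4 false calls. The simulated values were independent between genes and arrays and carried no slide effect. The real arrays had an estimated correlation of 0.408 within slides, so these rates do not carry over to the real comparisons. On simulated arrays of 41775 probes the partition placed the left end of 58 of 60 planted gains of 20 or more probes within 2 probes. At a noise SD of 0.2, it recovered 0 of 5 gains of 10 probes at a log2 of 0.38. The number of arrays limits the precision of every group value.

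Genes were named by a rule set before the data were examined: SUL1 and its measured neighbours, up to 10 genes with the highest and 10 with the lowest values among called genes whose 4 populations lie on the same side, the genes at segment ends, and up to 4 called members of each other list. Alternatives were another background correction (normexp on median signals, since the files hold no mean signals), loess, the deposited log2 table, centring on the mode, a filter on dim probes, the median over probes, other segment settings, the slide as a fixed or random block, other limma settings, and each array left out in turn. Keeping uneven spots, naming genes on X and XI, leaving out the 3 arrays of slide 1, and counting mitochondrial segments were chosen after the data were seen. The arrays lie on 4 slides, scanned on 2 days: slide 1 holds populations 1, 9 and 12 and was scanned on day 1, slide 2 holds 6, 7, 8 and 10, slide 3 holds 11, and slide 4 holds 2, 3, 4 and 5.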

Results

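Copy number was measured along the genome of 12 evolved diploid yeast populations on day 33, with 4 populations of each of 3 genotypes: wild type, heterozygous and homozygous for a deletion of ARS228. ARS228 is a replication origin next to SUL1, which encodes a high-affinity sulfate permease, near the right end of chromosome II. Each array held 41775 probes with a median spacing of 257 bp, and its noise, taken from neighbouring probes, had an SD between 0.091 and 0.204 on the log2 scale. At least 98.98% of the probes of every array were well above background.

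The first comparison sets each genotype against FY4 and asks which parts of the genome the populations had gained or lost. SUL1 was amplified in all 12 populations. Its log2 ratio to FY4 was 2.29 ± 0.27 (SD, n = 4) in wild type, 2.92 ± 0.41 (SD, n = 4) in the heterozygous deletion and 2.77 ± 0.29 (SD, n = 4) in the homozygous deletion, or 4.89, 7.59 and 6.8 times FY4. Taken as copies per diploid cell, SUL1 stood between 7.5 (population 2) and 11.6 (population 3) in wild type, between 10.3 (population 8) and 19.0 (population 6) with the heterozygous deletion, and between 10 (population 11) and 15.4 (population 10) with the homozygous deletion. By limma the adjusted p of SUL1 was 5.5e-06, 4.3e-07 and 8.1e-07 in that order, and no SUL1 probe was saturated on any array. With normexp background correction of the median signals the same 3 means rose to 4.10, 4.56 and 4.64. That setting also left out the scanner's spatial and dye corrections. The copy numbers therefore depend on the signal processing, and the part of the background correction alone was not tested.

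The genes between SUL1 and the end of chromosome II rose with it. PCA1, which encodes a cadmium-transporting P-type ATPase, had log2 ratios of 2.32 ± 0.30 in wild type, 2.92 ± 0.43 with the heterozygous deletion and 2.82 ± 0.36 with the homozygous deletion (SD, n = 4 each). PHO89, a sodium and phosphate cotransporter gene, stood at 2.36, 2.87 and 2.79. The maltose genes MAL33, a transcription activator, and MAL31, a permease, stood at 2.17, 2.74 and 2.59 and at 2.22, 2.82 and 2.67. To the left of SUL1, the vacuolar permease gene VBA2 reached 2.08, 1.77 and 2.39, with an SD of 1.03 among the heterozygous populations. BSD2, a metal homeostasis gene, was called only with the homozygous deletion (1.80 ± 0.67, SD, n = 4, limma adjusted p 0.037). It lost that call when any homozygous population was left out, at 2.10 without population 9, 1.64 without population 10, 1.61 without population 11 and 1.84 without population 12, and also without population 5 or 8, where it stayed at 1.80. In the heterozygous deletion VBA2 lost its call without population 5 (1.88), 7 (1.42) or 8 (1.58), and it lost it with the slide as a fixed (1.53) or random block (1.63). In wild type it also lost its call with either block, at 2.32 and 2.22, and in the homozygous deletion it lost it without the 3 arrays of slide 1 (2.65). BSD2 lost its call with either block, at 1.55 and 1.66. Of 25 other settings, VBA2 kept its heterozygous call in 18 and BSD2 its homozygous call in 14. At the BSD2 probe at 783099, populations 1 to 4 stood at 2.27, 1.86, -0.21 and -0.02. Populations 5 to 8 stood at 1.16, 0.1, 2.71 and 2.32 there, and populations 9 to 12 at 0.98, 2.72, 2.31 and 1.8. The BSD2 call alone therefore does not set the homozygous deletion apart. Farther left, SNF5, APM3, YBR287W, APE3, YBR284W, SSH1 and DUG2 were called in no genotype, since only some populations carried them.

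**Figure D1:**
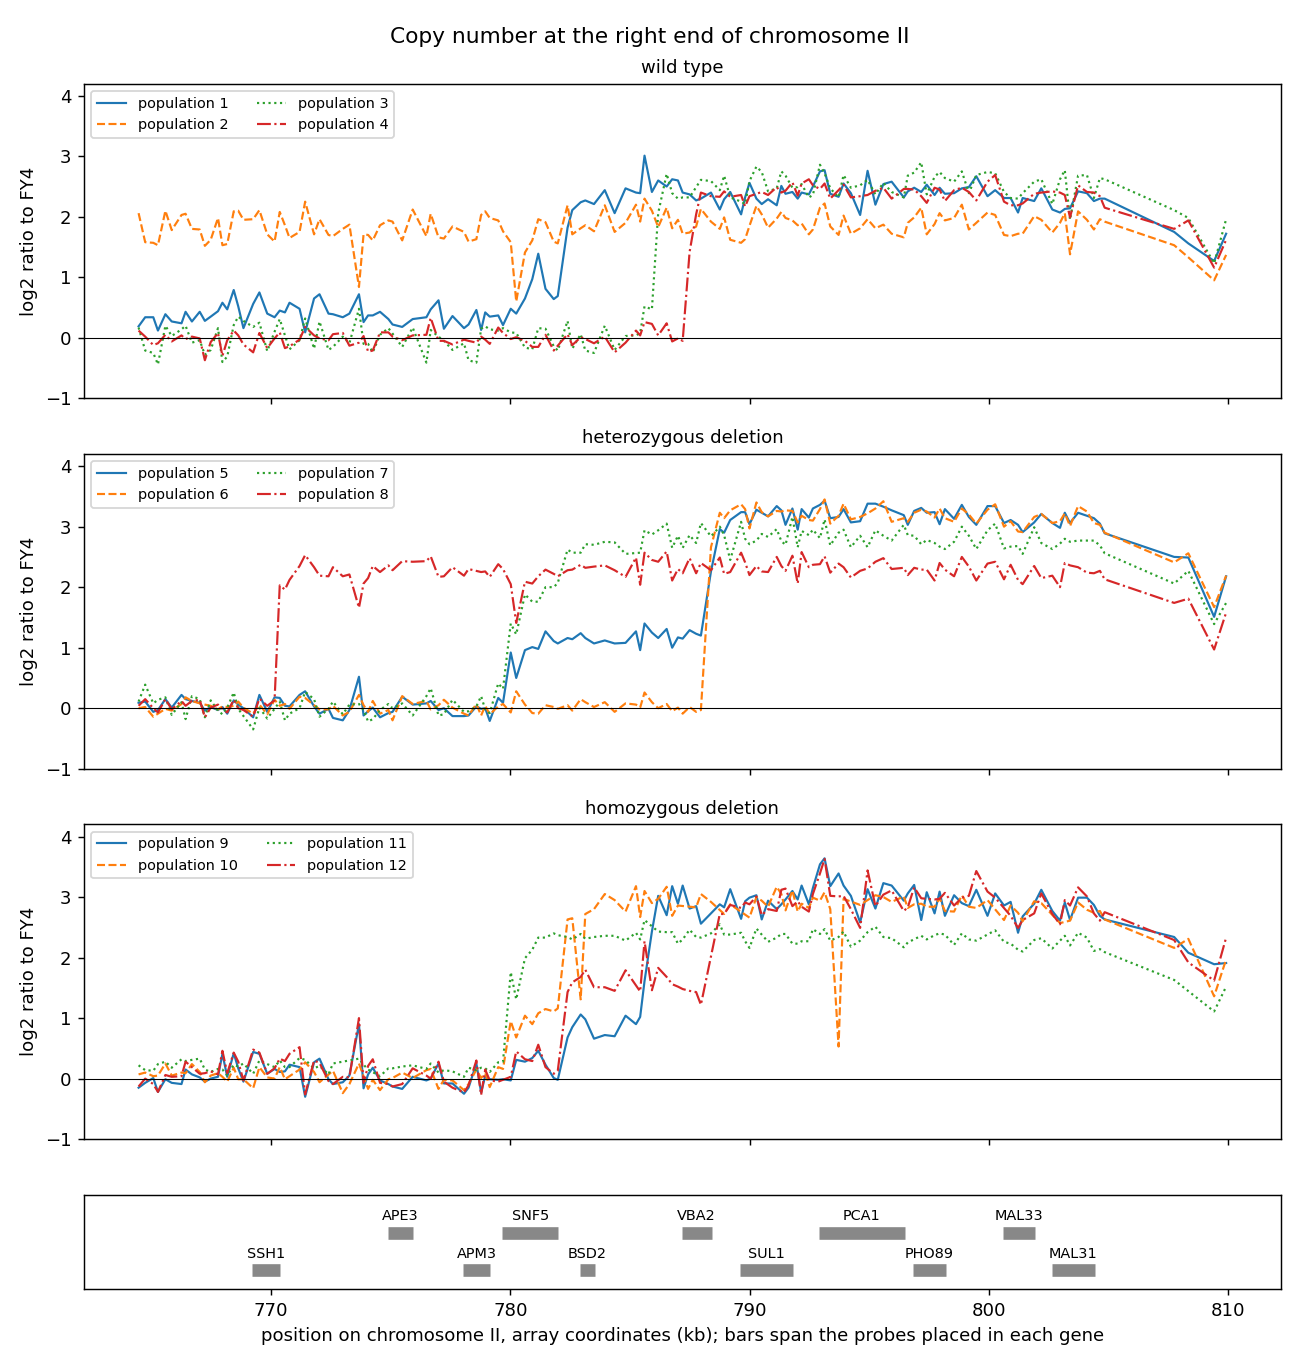
Log2 ratio to FY4 of each probe (y axis) along the right end of chromosome II in kb of the array's coordinates (x axis), 1 line per population and 1 panel per genotype, with the probes of named genes as bars. The amplified part starts at different places left of SUL1, from 770332 in population 8 to 788350 in population 6, while population 2 is amplified across the whole window and population 1 is slightly raised left of its main step.

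The left end of the amplicon differed between populations, and in all 12 the gain reached the last probes of chromosome II at 809934. With runs of at least 5 probes counted as segments, the gain began at 684424 in population 1, at 581538 near UMP1 in population 2, at 786145 in population 3, left of VBA2, and at 787457 in VBA2 in population 4. Among the heterozygous populations it began at 779987 within SNF5 in populations 5 and 7, at 788350 in population 6 and at 770332 near SSH1 in population 8. Among the homozygous populations it began at 782358 beside SNF5 in populations 9 and 12 and at 779987 in populations 10 and 11. Several populations rose in more than 1 step: population 12 stood at 1.54 left of a step at 788719 and at 2.77 right of it, and population 5 stood at 1.24 left of a step at 788350 and at 2.71 right of it. In population 1 the stretch from 684424 to 780272 was raised by 0.38 only.

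The second comparison asks whether the loss of ARS228 went with another copy number of SUL1 or another amplicon. SUL1 was higher by 0.63 with the heterozygous deletion than in wild type, and 3 of its 4 populations lay above every wild-type population. With the homozygous deletion it was higher by 0.48, again with 3 of 4 populations above every wild-type population, and the homozygous minus heterozygous difference was -0.16. With 1 population left out at a time these 3 differences ranged from 0.51 to 0.82, from 0.35 to 0.62 and from -0.34 (without population 8) to -0.01 (without population 11). By exact permutation tests, p was 0.086, 0.086 and 0.54, or 0.13, 0.13 and 0.54 after adjustment, so none of the 3 differences was past the threshold. The limma adjusted p was 0.29, 0.46 and 0.69. With the slide as a fixed block the differences were 0.78, 0.75 and -0.04. Within slide 4, population 5 lay 0.94 above the mean of wild-type populations 2, 3 and 4. Within slide 1, homozygous populations 9 and 12 lay 0.57 above wild-type population 1, and within slide 2 homozygous population 10 lay 0.12 above heterozygous populations 6, 7 and 8. These within-slide values rest on 1 population on at least 1 side and carry no test.

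**Figure D2:**
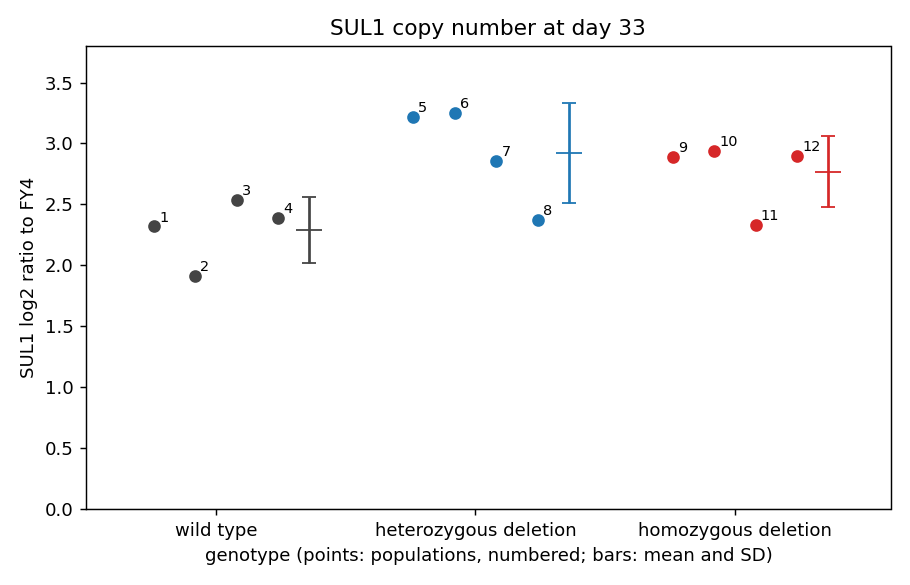
SUL1 log2 ratio to FY4 (y axis) of each population (points, with population numbers) by genotype, with the mean and SD of the 4 populations as bars. Wild-type populations lie between 1.91 and 2.54, and populations 8 and 11 lie within that range.

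The amplicon was longest in wild-type population 2, at 228.4 kb. Called from segments of at least 10 probes, it spanned 17.2 to 228.4 kb in wild type, 14.9 to 34.3 kb with the heterozygous deletion and 22.1 to 23.0 kb with the homozygous deletion. This rule counted the end of chromosome II, to 809934, in populations 2 and 3 only. In the others the counted length stopped at 804660, or at 804409 in population 11. In population 5 it also left out the gained segment from 781436 to 787988. These lengths are therefore not measured alike in all populations. The mean log10 length in kb was 1.58 ± 0.52, 1.32 ± 0.16 and 1.35 ± 0.01 (SD, n = 4 each). The heterozygous minus wild-type difference was -0.26, the homozygous minus wild-type difference was -0.23 and the homozygous minus heterozygous difference was 0.03. Exact permutation p was 0.46, 0.69 and 0.89, or 0.89 for each pair after adjustment. Without population 2 the heterozygous minus wild-type difference was -0.00 and the homozygous minus wild-type difference turned to 0.03. With runs of 5 probes allowed, the lengths ran from 22.5 to 228.4 kb, from 21.6 to 39.6 kb and from 27.6 to 29.9 kb, and the mean log10 length in kb was 1.80, 1.47 and 1.46. Population 1 then spanned 125.5 kb, because its raised stretch from 684424 to 780272 joined the amplicon, and without population 2 the wild-type mean was 1.61 in this setting.

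The interval between SUL1 and PCA1, where ARS228 lies, was amplified as much as its flanks in every genotype. Its 4 probes stood at 2.29 ± 0.32, 2.87 ± 0.38 and 2.78 ± 0.32 (SD, n = 4 each). Against the mean of SUL1 and PCA1 on the same array they stood at -0.02 ± 0.09, -0.05 ± 0.05 and -0.01 ± 0.05. The heterozygous minus wild-type difference of the interval was 0.58, the homozygous minus wild-type difference 0.49 and the homozygous minus heterozygous difference -0.09, with exact permutation p of 0.11, 0.11 and 0.6, or 0.17, 0.17 and 0.6 after adjustment. Relative to its flanks, the same 3 differences were -0.03, 0.01 and 0.04, with exact permutation p of 0.54, 0.89 and 0.34, or 0.81, 0.89 and 0.81 after adjustment. No drop marked the homozygous deletion. Where the deleted part lies relative to the 4 probes is not given in the sources used here, so the probes check nothing about the genotype labels.

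Outside the SUL1 region, population 2 carried a gain of nearly the whole of chromosome XVI, from 13168 to 942842, with a chromosome median of 0.38 or 2.61 apparent copies. Chromosome XVI at 3 copies in every cell would give 0.58. Chromosome II as a whole stood at 0.17 in population 11. Population 7 had 18 lost nuclear segments that together held 118.9 kb. They formed 10 separate stretches, since 14 of them adjoined as graded steps of 6 stretches, such as -0.44, -1.24 and -0.54 from 264292 to 279265 on chromosome VII. The deepest segments ran from 270522 to 273532 on chromosome VII, between SOH1 and MET13, at -1.24, and from 636691 to 641087 on chromosome X at -1.08. The stretch from 148727 to 151480 on chromosome III, next to SRD1, was called lost in populations 4, 5, 6 and, with 1 more probe, 12, and stood at -0.28 ± 0.15 (SD, n = 12) over all populations. Populations 2 (-0.41) and 3 (-0.38) lay below population 4 (-0.32) there without a call, so the calls do not set population 4 apart from them. The mitochondrial genome had a median between -0.18 (population 1) and 0.36 (population 8). Its mean over populations was 0.11 ± 0.21 in wild type, 0.17 ± 0.16 with the heterozygous deletion and 0.09 ± 0.10 with the homozygous deletion (SD, n = 4 each). The 3 mitochondrial differences, in the order used for SUL1, were 0.06, -0.02 and -0.08, with exact permutation p of 0.63, 0.86 and 0.43 and an adjusted p of 0.86 for each.

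**Figure D3:**
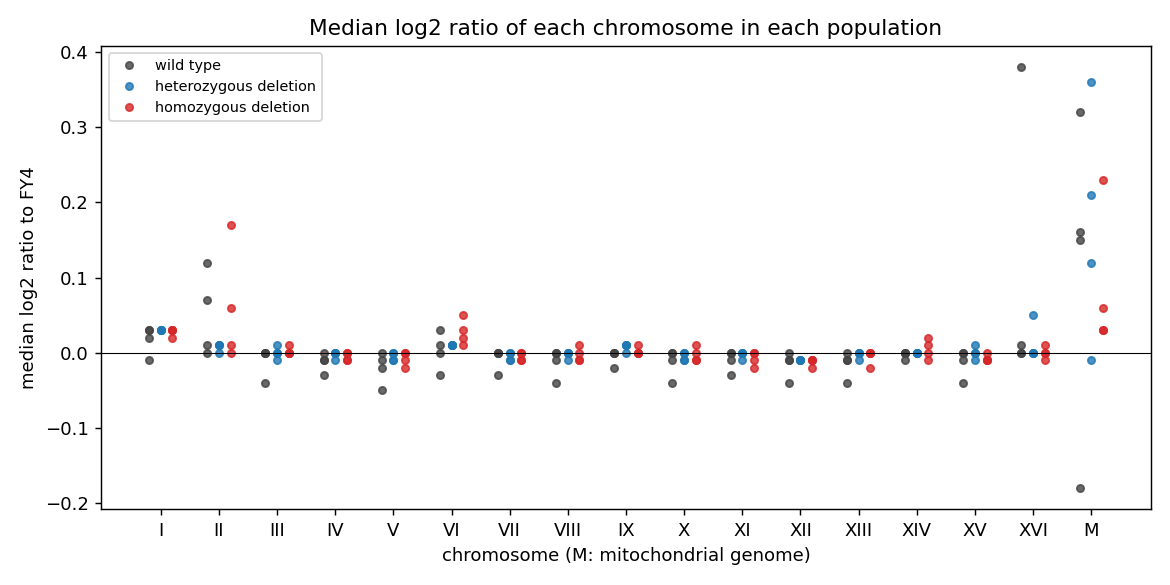
Median log2 ratio to FY4 (y axis) of each chromosome (x axis, M for the mitochondrial genome) in each population, with 1 point per population coloured by genotype. Chromosome XVI of wild-type population 2 stands at 0.38 and chromosome II of homozygous population 11 at 0.17, while the mitochondrial genome runs from -0.18 to 0.36.

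Gained nuclear segments summed to 354.3 ± 546.3 kb in wild type, 24.6 ± 7.7 kb with the heterozygous deletion and 97.5 ± 98.3 kb with the homozygous deletion (SD, n = 4 each). The heterozygous minus wild-type difference was -329.7 kb, the homozygous minus wild-type difference -256.8 kb and the homozygous minus heterozygous difference 72.9 kb, with exact permutation p of 0.26, 0.69 and 0.086, or 0.39, 0.69 and 0.26 after adjustment. Without population 2, with its gain of XVI, the homozygous minus wild-type difference turned to 12.9 kb and the heterozygous minus wild-type difference was -60.0 kb. The homozygous minus heterozygous difference fell to 25.7 kb without population 9 and to 7.2 kb without the 3 arrays of slide 1. Populations 9 and 12, both on slide 1, held 25 and 11 gained nuclear segments, and wild-type population 1, the other array of slide 1, held 12, against 1 to 3 on each of the 9 arrays of the other slides. The segments from 19615 to 25873 and from 388671 to 394168 on chromosome IX were gained in all 3 arrays of slide 1 and called in no other population. Lost nuclear segments summed to 0.7 ± 1.4, 31.1 ± 58.5 and 0.8 ± 1.5 kb. Their differences were 30.4, 0.1 and -30.3 kb, with exact permutation p of 0.37, 1.0 and 0.37, or 0.56, 1.0 and 0.56 after adjustment. Without population 7 the heterozygous minus wild-type difference was 1.1 kb and the homozygous minus heterozygous difference -1.1 kb. With mitochondrial segments counted, the 3 gained differences were -307.2, -252.9 and 54.3 kb and the 3 lost differences 25.1, -8.7 and -33.8 kb.

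Gene by gene, limma called 22 genes higher and 22 lower than FY4 in wild type, 10 higher and 0 lower with the heterozygous deletion, and 39 higher and 0 lower with the homozygous deletion. Without a dye swap, small differences to FY4 may hold a dye effect of the probes, which was not separated. In wild type, VBA2, SUL1, PCA1, PHO89, MAL33 and MAL31 led, followed by the subtelomeric genes YIR043C (0.48 ± 0.13) and COS8 (0.47 ± 0.14) and by BRR1 (0.27 ± 0.25) and YPR196W (0.26 ± 0.18) on chromosome XVI. BRR1, a spliceosome gene, stood at 0.16 and lost its call without population 2, and it lost the call at 0.27 without population 3, 5, 6 or 8. YPR196W lost its call without population 2 (0.18). YIR043C lost its call without population 1 (0.42), 2 (0.52) or 3 (0.46), and COS8 without any 1 of the 4 wild-type populations (0.41 to 0.52). With the slide as a fixed block YIR043C, COS8, BRR1 and YPR196W all lost their calls (0.30, 0.31, 0.20 and 0.20), and with the slide as a random block they lost them too. SPR28, a meiotic septin gene, was lowest at -0.33 ± 0.13 (SD, n = 4, limma adjusted p 0.0059), followed by RRN9, ERG4, YPI1, AIM33, SDH4, ANK1, GLE2, YLR225C and YNL234W between -0.27 and -0.22. None of these 10 kept its call with the slide as a fixed or random block, where SPR28 stood at -0.21 and -0.27, and RRN9 also lost it without population 2 (-0.26) or 3 (-0.21). Without population 2 YNL234W (-0.19), YLR225C (-0.19) and GLE2 (-0.20, short of the size threshold before rounding) lost it too, and YLR225C also without population 3 (-0.19). With the heterozygous deletion the mitochondrial rRNA genes 15S_RRNA (0.37 ± 0.11) and 21S_RRNA (0.33 ± 0.10), RGM1 (0.23 ± 0.02) and POR2 (0.22 ± 0.08) were called. 21S_RRNA lost its call without population 8 (0.28). 15S_RRNA lost it without each of the 4 heterozygous populations in turn (0.32 to 0.40) and without population 3, 4, 9, 11 or 12, and POR2 without population 5 (0.21), 6 (0.19) or 8 (0.23). With the slide as a fixed block 15S_RRNA, 21S_RRNA and POR2 lost their calls (0.21, 0.24 and 0.25), as they did with it as a random block, where RGM1 kept its own, and after loess none of the 4 was called. With the homozygous deletion YIR043C (0.61 ± 0.36), COS8 (0.59 ± 0.37) and HPF1 (0.32 ± 0.21), a cell wall gene, followed the genes of chromosome II. Without population 9 YIR043C, COS8 and HPF1 lost their calls, at 0.50, 0.49 and 0.28, and without population 12 they lost them too, at 0.51, 0.47 and 0.25. Without the 3 arrays of slide 1 they lost them at 0.29, 0.27 and 0.14, and with the slide as a random block HPF1 lost its call (0.26).

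The numbers of called genes changed when single arrays were left out and when the slide entered the fit. The wild-type number of 44 became 97 without population 1, 13 without population 2, 17 without population 3 and 87 without population 4. The heterozygous number of 10 became 16 without population 2 and 6 without population 8, and the homozygous number of 39 became 15 without population 9, 12 without population 12, 100 without population 10 and 80 without population 11. With the slide as a fixed block, limma called 5 genes in wild type, 16 with the heterozygous deletion and 27 with the homozygous deletion, and with the slide as a random block 5, 6 and 18. No slide holds all 3 genotypes, so slide and genotype are partly confounded. With the fixed block the standard error of SUL1 in wild type rose from 0.15 to 0.2. A call lost with a slide block may therefore reflect lower precision, and does not show that the call came from the slide. Centring on the mode changed the wild-type split to 17 higher and 37 lower. The 22 lower genes of wild type became 8 after loess. They became 7 without population 2 and 10 without population 3, the 2 arrays with the widest dye scaling, but 50 without population 1 and 32 without population 4. Whether the dye scaling gave the lower calls was not tested.

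Between genotypes, limma called 0 genes in each of the 3 comparisons, SUL1 and its neighbours included. At an unadjusted p under 0.05 there were 482 genes for heterozygous minus wild type, 414 for homozygous minus wild type and 311 for homozygous minus heterozygous, among 3893 tested. With the slide as a fixed or random block limma also called 0 genes in each. Without population 1 it called 12 genes for heterozygous minus wild type and 56 for homozygous minus wild type. After loess it called 1 gene for heterozygous minus wild type.

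Of the gene lists fixed in advance, the SUL1 neighbourhood (14 of 22 genes measured) had a median log2 against FY4 of 0.79 in wild type, 1.36 with the heterozygous deletion and 1.30 with the homozygous deletion. Its called members were VBA2, SUL1, PCA1, PHO89, MAL33 and MAL31 in every genotype, with BSD2 as a further gene in the homozygous deletion. With 6, 6 and 7 of the 14 genes called, the medians against FY4 mix called and uncalled genes. For this list, heterozygous minus wild type gave a median difference of 0.28 and a mean of 0.21 (camera adjusted p 0.16). Homozygous minus wild type gave 0.28 and 0.06 (camera adjusted p 0.87), and homozygous minus heterozygous -0.15 and -0.15 (camera adjusted p 0.28). These adjusted p are at the preset correlation. Between genotypes, no list had a called member, over all genes or adjusted over the list alone. The mitochondrial genome list (20 genes measured) was the only list that camera called at the preset correlation, lower by a median of -0.10 with the homozygous than with the heterozygous deletion (adjusted p 0.0026), and with the estimated correlation of 0.70 its adjusted p was 0.79. A probe in overlapping genes counted for each of them. Populations 9 and 12, with mitochondrial medians of 0.03 each, lie on slide 1, which holds no heterozygous population. Populations 10 and 11, on other slides, stood at 0.23 and 0.06. Slide and genotype were not separated for this list. Sulfur uptake and assimilation, other nutrient transporters, origin licensing and firing, and recombination and fork protection had median differences between -0.02 and 0.04, and ribosomal protein genes between -0.05 and 0.03. Median and mean differed in sign for origin licensing in heterozygous minus wild type (0.01 and -0.02) and for recombination in homozygous minus heterozygous (-0.02 and 0.02), and camera ranked the sulfur list downward in homozygous minus wild type at a median of 0.01. Against FY4, SUL1 was the 1 called member of the sulfur list and PHO89 the 1 called member of the transporter list, and no origin, recombination or ribosomal protein gene was called. Subtelomeric families had 3 higher and 1 lower member in wild type, 2 higher with the heterozygous deletion and 5 higher with the homozygous deletion, MAL33 and MAL31 among them in each. The others named were COS8 in wild type and the homozygous deletion, SNO1 in wild type (-0.22 ± 0.14, SD, n = 4) and FLO11 in the homozygous deletion (0.29 ± 0.18, SD, n = 4). This list was drawn up by the names of gene families, so a member such as SNO1 need not lie near a chromosome end. SNO1 lost its call without population 2 or 3 (-0.18 each) and with the slide as a fixed or random block (-0.21 each), and FLO11 lost it without population 9 (0.24) or 12 (0.23) and without the 3 arrays of slide 1 (0.13). The mitochondrial genome list had 3 higher members in wild type, 2 with the heterozygous deletion and 1 with the homozygous deletion, and 0 lower. In wild type these were 15S_RRNA (0.33 ± 0.25), 21S_RRNA (0.24 ± 0.14) and SCEI (0.20 ± 0.07), an intron endonuclease gene, with the heterozygous deletion 15S_RRNA and 21S_RRNA, and with the homozygous deletion SCEI (0.22 ± 0.15; SD, n = 4 each). In wild type all 3 lost their calls with the slide as a fixed block (0.24, 0.19 and 0.11) or random block, without population 2 (0.28, 0.19 and 0.18) and without population 3 (0.28, 0.22 and 0.22), and 15S_RRNA and SCEI also without population 4 (0.31 and 0.19). In the homozygous deletion SCEI lost its call without population 9 (0.20) or 12 (0.17), without the 3 arrays of slide 1 (0.10) and with the slide as a random block (0.22), and after loess SCEI turned to -0.03 in wild type and -0.02 in the homozygous deletion. Of 25 other settings, 15S_RRNA kept its wild-type call in 18, 21S_RRNA in 19 and SCEI in 14, so settings beyond those named here lost these calls too. The lists of tandem repeats, the 2-micron plasmid and mating-type genes had 0 genes with 3 probes.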

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

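The tests on the places of the left steps and on the gains outside chromosome II were chosen only after the results were seen, while those on population 7 were set before the channels were looked at. In each genotype, a population was singled out where its gap to the nearest of the other 3, divided by the range of all 4, passed Dixon's limit. This happened in 19 of 72 groups of values, and chance alone gives about 1 in 20. Many of these values are not independent, since neighbouring genes share 1 amplicon, so the count does not measure an excess over chance.

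Population 2 stood apart among the wild-type populations. Its gap was 0.875 of the range for the log10 amplicon length (2.36 against 1.24 to 1.38), 0.834 for gained kb (1163.3 against 17.2 to 207.6), 0.986 for the median of chromosome XVI (0.38 against 0.00 to 0.01), 0.882 for APE3 (1.90 against 0.03 to 0.25), 0.832 for the ARS228 interval (1.81 against 2.39 to 2.51) and 0.833 for PCA1 (1.87 against 2.42 to 2.53). Population 8, whose amplicon began near SSH1, stood apart among the heterozygous populations for YBR284W (0.97, at 2.28), APE3 (0.992, at 2.37), YBR287W (0.97, at 2.30) and APM3 (0.97, at 2.24), with the other 3 between -0.07 and 0.06, and for the median of chromosome XVI (0.989, at 0.05). Population 11 was lowest of the homozygous populations for SUL1 (0.916, 2.33 against 2.89 to 2.94) and MAL33 (0.855, 2.20 against 2.67 to 2.75) and highest for YBR284W (0.944, at 0.20) and APM3 (0.842, at 0.13). These 2 high values lie near its chromosome II median of 0.17. Without population 11 the homozygous minus wild-type difference of SUL1 was 0.62. The mitochondrial median was highest in population 10 (0.841, 0.23 against 0.03 to 0.06). Lost kb singled out population 4 in wild type (1.0), population 7 in the heterozygous deletion (0.977, 118.9 kb against 0.0 to 2.8) and population 12 in the homozygous deletion (1.0), where the value of 1.0 arises because the other 3 populations had no called nuclear lost segment. Population 4 owes this to 1 segment on chromosome III, where populations 2 (-0.41) and 3 (-0.38) lay lower than population 4 (-0.32) without a call, so it does not stand apart there.

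Population 7 had 18 lost nuclear segments in 10 separate stretches, most of them graded dips such as that around SOH1 and MET13, that were called lost in no other population. Over their 444 probes its Cy3 signal, the FY4 reference, deviated by 0.02 from the mean of the other 8 arrays of the same scan day, so a raised reference signal is argued against. Its Cy5 signal deviated by -0.40, while each of the other 8 arrays deviated by -0.10 to 0.05. These probes were chosen for a low ratio on this array. With Cy3 near its mean, a low Cy5 follows and is not a separate test. The dips thus lie in Cy5, and less labelled population DNA at these places may explain them. The mean distance of these probes on the array lay at the 34.1th percentile of 1000 random probe sets, which argues against a defect of 1 part of the array. Whether the DNA was lost in part of the population or in its preparation or labelling stays open, and no biological explanation was tested.

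Left of SUL1, several populations stepped up in the same gap between probes: populations 5, 7, 10 and 11 between 779720 and 779987, populations 1, 7, 9, 10 and 12 between 782008 and 782358, and populations 5 and 6 between 787988 and 788350, with population 12 in the next gap, while populations 1, 2 and 11 (780272 to 781134) and populations 3 and 9 (785632 to 786145) stepped in neighbouring gaps only. From left to right at these 5 places, populations 2 and 8, which are amplified on both sides, stepped by -0.56, 0.41, 0.15, -0.04 and -0.04 on average. This argues against a probe response at the last 3 places, and shows at -0.56 that the probes respond unusually but not as a rise. Near the place of 0.41, the probe at 780213 read 0.60, 1.41 and 1.31 in populations 2, 8 and 11, lower than the probes on both sides. That probe lies among the 3 probes before the steps of populations 2 and 11 there. Population 2 read 1.94 and 1.76 at 779461 and 779661, left of that probe, and 1.61 and 1.96 at 780884 and 781134, right of it. These values argue against a rise in copies there in population 2, although its step was counted. The step of population 11 may be a probe response. Of 10000 random placements of the steps, 0 gave as many pairs of populations in the same gap as the 16 found, and 2 gave as many as the 21 found with the next gap allowed, so chance placement is argued against. With the place from 780272 to 781134 left out, 19 pairs were found with the next gap allowed, and 2 of 10000 placements gave as many. The number of wild-type populations in the same gap as a deletion population was 1 between 782008 and 782358 (population 1) and 0 at the other 4 places, so the deletion genotype stays open as a cause. The 5 populations that stepped between 782008 and 782358 lie on 2 slides, with 1, 9 and 12 on slide 1 and 7 and 10 on slide 2. Sequence at these places that favours the rearrangement, variants already present in a shared founder culture, DNA carried between populations or samples, and the slide all remain possible and were not tested.

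The right end of chromosome VII, from 1079004 to 1084229, was higher than FY4 in all 12 populations (1.14 ± 0.27, SD), and COS8 and YIR043C were higher on other chromosomes. Over the 9 arrays of scan day 2 the VII end correlated with SUL1 at r = 0.96 (permutation p 3e-05) and rho = 0.98 (permutation p 8e-05), with r = 0.94 after leaving out the 2 arrays farthest in SUL1, and over all 12 at r = 0.83 (permutation p 0.0014) and rho = 0.72 (permutation p 0.011). The adjusted p over the 8 relations computed was 0.00024 for r on scan day 2. Signal from sequence shared with the amplified end of II is consistent with this, but a true second gain that tracks it is not excluded. For COS8 and YIR043C, r was 0.54 (permutation p 0.13), with rho of 0.58 (permutation p 0.11), and 0.01 without the 2 farthest arrays, so the same explanation stays undecided. Slide 1 as the whole source is argued against, since the means over the other slides were 1.05 for the VII end and 0.38 for COS8 and YIR043C, although the latter stood at 0.82 on slide 1.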

How the results depend on the processing

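Leaving out slide 1, keeping uneven spots, naming genes on X and XI and counting mitochondrial segments were chosen only after the results were seen. SUL1 against FY4 kept its direction and its call in every setting tried in each genotype (2.05 to 4.10 in wild type, 2.76 to 4.56 with the heterozygous and 2.57 to 4.64 with the homozygous deletion). The higher SUL1 with either deletion than in wild type kept its direction and stayed short of the threshold in every setting (0.45 to 0.82 and 0.35 to 0.75). Where a value below turned or moved, the cause was not tested unless it follows from fewer arrays or other genes tested.

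With normexp on median signals, homozygous minus heterozygous turned for SUL1 (0.08) and the ARS228 interval (0.12), and homozygous minus wild type turned for amplicon length (0.19), lost kb (-7.7) and the interval against its flanks (-0.03). Called genes against FY4 became 9, 16 and 6 in wild type, heterozygous and homozygous deletion, lists called became 2 (0 with the estimated correlation), and the median array noise rose to 0.307. Loess turned SCEI against FY4 to -0.03 in wild type and -0.02 in the homozygous deletion, and gave 20, 6 and 18 genes, 1 gene for heterozygous minus wild type, and -0.05 for the homozygous minus heterozygous length. That length also turned with only bright probes (-0.01), a penalty of 15 (-0.01) or 60 (-0.02), and segments of 5 or more probes (-0.01). Mode centring called 79 genes in the homozygous deletion and 6 lists (1 with the estimated correlation), and gave 0.05 for mitochondrial homozygous minus wild type. A running median gave -8.6 for lost kb in homozygous minus wild type, and counting mitochondrial segments gave -8.7. Against its flanks, the interval in homozygous minus wild type turned with only bright probes (-0.01) and with the median over probes (-0.05), which also turned homozygous minus heterozygous (-0.02). With the slide as a fixed block 5 and 16 genes were called in wild type and heterozygous deletion, with 5 lists (0 with the estimated correlation), and as a random block 5, 6 and 18 genes in the 3 genotypes. Genes with 1 or more probes gave 121, 28 and 84, a size threshold of 0.3 gave 10 in wild type and 10 in the homozygous deletion, and no size threshold 469, 86 and 396. With genes on X and XI 2 lists were called (0 with the estimated correlation). Without slide 1 there were 91, 20 and 13 genes, 9 for heterozygous minus wild type and 3 lists (0 with the estimated correlation), lost kb in homozygous minus wild type was -0.9, and mitochondrial heterozygous minus wild type was -0.04.

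With 1 population left out at a time, called genes ranged from 13 to 97 in wild type, 6 to 16 in the heterozygous and 12 to 100 in the homozygous deletion, 0 to 12 for heterozygous minus wild type, 0 to 56 for homozygous minus wild type and 0 to 0 for homozygous minus heterozygous, and lists from 1 to 4 (0 with the estimated correlation in each). SUL1 ranged from 0.51 to 0.82 for heterozygous minus wild type, from 0.35 to 0.62 for homozygous minus wild type and from -0.34 to -0.01 for homozygous minus heterozygous. Amplicon length ranged from -0.38 to -0.00 for heterozygous minus wild type, from -0.34 to 0.03 for homozygous minus wild type and from -0.01 to 0.11 for homozygous minus heterozygous, and gained kb from -369.1 to 12.9 and lost kb from -0.7 to 0.8 for homozygous minus wild type. The ARS228 interval ranged from -0.27 to 0.07 for homozygous minus heterozygous. Against its flanks it ranged from -0.06 to 0.01 for heterozygous and from -0.02 to 0.05 for homozygous minus wild type. The mitochondrial median ranged from -0.04 to 0.13 and from -0.12 to 0.05 for the same pairs. No paired analysis was possible because the replicate numbers were given in order of deposition and tie no population of 1 genotype to a population of another. Of 1075 results of single named genes under other settings, 899 kept direction and call, 174 fell short of the adjusted p or of the size threshold and 2 turned. PCA1, PHO89, MAL33 and MAL31 kept their calls in all 300 of theirs. Nearly all probes were well above background, yet the normexp values show that the size of the ratios and the calls depend on the signal processing. That setting changed the signal used, the spatial and dye corrections and the background together, so the background alone was not tested.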

Other observations

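The tests in this part were chosen only after the results were seen. The gene at the silent mating locus, HMRA1, has 2 probes and was therefore not in the gene-wise fit. It stood at -0.44 ± 0.04 (SD) over the 9 arrays of slides 2 to 4 and at -0.07 over the 3 arrays of slide 1. A diploid with both mating types compared with a haploid that carries the MATa allele would give -0.42. The mating types of the populations and the ploidy of the reference are not given in the sources used here. Whether the slide 1 arrays carried the same FY4 DNA as the others is therefore not settled, and with another reference the ratios of populations 1, 9 and 12 would stand for something else. ENA1, a sodium pump gene in a tandem repeat, stood at -0.12 ± 0.06 on slides 2 to 4 and at -0.02 on slide 1, also with 2 probes.

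With lengths from segments of at least 10 probes, SUL1 tended to be lower where the amplicon was longer. Those lengths are not measured alike in all populations. Over the 12 populations r between log10 amplicon length and SUL1 was -0.69 (permutation p 0.0026, adjusted p 0.0069 over 8 relations) and rho was -0.75 (permutation p 0.0063, adjusted p 0.022). Without the 2 populations farthest in length r was -0.51, and within scan day 2 it was -0.74 (permutation p 0.0043, n = 9); the 3 arrays of scan day 1 are too few for a value. With 5-probe segments r was -0.67 (permutation p 0.0091, adjusted p 0.015), with rho of -0.60 (permutation p 0.043, adjusted p 0.069), and -0.24 without the 2 farthest, so in that setting the relation rests on populations 1 and 2. In that setting within scan day 2, r was -0.64 (permutation p 0.036, adjusted p 0.048), rho -0.58 (permutation p 0.1, adjusted p 0.13), and r 0.06 without the 2 farthest. A longer amplified unit may be kept at fewer copies, but the relation depends on how segments are called, genotype and length were not separated, and it was found on these data.

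No gene was called between genotypes, so every split of the arrays gives at least as many, and the splits say nothing about chance for any of the 3 comparisons. For heterozygous minus wild type, all 35 of 35 splits of the 8 arrays gave at least the real 0 genes, and the highest other split gave 0. For homozygous minus heterozygous, the numbers were the same: 35 of 35 splits, 0 and 0. For homozygous minus wild type, 35 of 35 splits gave at least the real 0 genes, and the highest other split gave 245, with populations 1, 9, 11 and 12 on 1 side. That split puts the 3 arrays of slide 1 together, which points to a structure of the samples by slide, and with the slide as a fixed block limma called 0 genes between these genotypes.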
